A study of Mus musculus with 2 samples.

How the data were processed

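Expression was measured in mouse fibroblasts on 2 single-colour Illumina bead arrays, 1 for control cells and 1 for cells on gold nanoparticles (AuNPs) exposed to an electromagnetic field (EMF). Per the labels' protocols, total RNA was extracted with Trizol and amplified to biotin-labelled cRNA with the Illumina TotalPrep kit. GenomeStudio 2011.1 is named in the submitters' processing notes. The authors deposited, for each of 25697 probes, a signal intensity on a linear scale that was not normalized between arrays. Beside each intensity the authors deposited a detection p-value, which falls in steps of 1 in 798. Any step between scanner output and these intensities is not given in the sources used here. The authors also deposited a table of log2 values. It equalled the quantile normalized log2 intensity of each array, with no background correction, to within 4.99988e-07, which settled its scale and the identity of its columns. Both of its columns have a median of 7.35. Arrays were assigned to conditions by the sample descriptions that head the intensity columns.

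Gene names came from the platform annotation supplied with the series. It gave 1 gene for 23978 probes and several genes for 0, and 1719 probes were left unnamed. Of the named probes, 23962 matched a gene of the GRCm38.p6 RefSeq table by Entrez number, and 0 symbols needed updating. No genome build is named with the array, so no coordinates are given.

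The intensities were background-corrected and quantile normalized with the neqc function of limma 3.58.1 in R 4.3.3. This function takes the mean and variance of the negative-control beads from the detection p-values, adds an offset of 16 and returns log2 values. A probe was called detected at a detection p under 0.01. Each gene was represented by its brightest probe among those detected on at least 1 array, which left 8651 genes. Of these, 8199 were detected on both arrays, 248 on the EMF and AuNP array alone and 204 on the control array alone. A gene detected on both arrays has a measured difference, EMF and AuNPs minus control. A gene detected on 1 array has a bound, "at least N-fold". The bound sets the bright value against the higher of the dim probe's own value and the lowest detected value of the dim array.

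With 1 array per condition there was no test between conditions and no p-value, and the number of arrays limits the precision. Genes were called by size, at a limit of 2-fold. As a yardstick for single genes, the robust SD (1.4826 times the median absolute deviation) of the differences was taken among genes of like brightness, in 20 equal bins. It was 0.65 (log2) in the dimmest bin, 0.42 in the next and 0.14 in the brightest. It holds real change as well as noise and does not replace replicates. A set of 48 gene lists was fixed before the data were examined, and 2 of their symbols matched no gene. The 41 lists with at least 5 detected genes were scored. The median difference of each was placed among the medians of 10000 random lists of the same size, matched on mean expression. A list stood apart above the 97.5th or below the 2.5th percentile. Of 41 lists of randomly drawn genes, about 1.03 would lie past each limit. These percentiles describe the 2 arrays and are no test between conditions. Genes that vary together between any 2 cultures move a list more often than random genes do.

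Genes named in the text were chosen by a rule fixed at the same time. It takes, per direction, the 12 largest measured differences and the 5 largest bounds, leaving out symbols that only number a transcript (1 such gene passed 2-fold). It also takes the 4 detected members of each list with the largest difference, and a fixed set of fibroblast, dopamine neuron, chromatin and reference genes. A gene outside this rule is named with a remark that it was chosen after its values were seen. The steps were tested on simulated arrays made from the control array, with noise set from the observed spread. They held 200 changed genes among 10314 detected, beside a list of 15 genes shifted by 0.5 (log2), which lay at percentile 100. Genes changed 2-fold passed the 2-fold limit in 49.3% of cases, those changed 3-fold in 95.5% and those changed 4-fold in 98.5%. Of 10099 unchanged genes, 74 passed the 2-fold limit. The simulated noise was normal with the robust SD of each brightness, so it holds no heavier tails. A fresh background draw was added to each array on top of this spread, which already holds background noise. Dim genes may therefore vary more than in the data, where 8651 genes were detected. Of 400 random lists of 15 unchanged genes, 5.5% lay past either percentile limit. This share follows from drawing genes with independent noise, so it checks the steps alone and does not cover lists whose genes vary together.

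Alternatives covered the background correction (normexp without negative controls and an offset of 50, or none), the normalization (median centring, cyclic loess, or the deposited log2 values), the detection limit (0.05, both arrays, or none), the mean of all probes of a gene, fold limits of 1.5 and 3, unmatched random lists, and the mean in place of the median. Without background correction, signals under 1 would have been set to 1. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.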

Results

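Gene expression was profiled in control mouse fibroblasts and in fibroblasts kept on gold nanoparticles (AuNPs) and exposed to an electromagnetic field (EMF). The series title places the comparison in work on EMF-mediated conversion of cells into dopamine neurons. The design holds 1 array of each condition and no array of AuNPs alone or EMF alone, so the values below describe the combined exposure in 1 sample. Neither array has a replicate, and no value carries a replicate error. The median intensity was 165 on the control array and 162 on the EMF and AuNP array. Of the 25697 probes, 12012 (46.7%) were detected on the control array and 11963 (46.6%) on the other. Detection began at an intensity of 187 on the first and 181 on the second.

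The 2 arrays were closely alike. The log2 intensities correlated across probes with r = 0.994, where probes are not independent replicates. Of the 8199 genes detected on both arrays, 94.1% differed by less than 1.5-fold. The robust SD of their differences was 0.23 on the log2 scale. Of 8651 detected genes, 45 were at least 2-fold higher with EMF and AuNPs and 42 at least 2-fold lower. These include 5 higher and 8 lower genes that were detected on 1 array only and have a bound.

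The largest measured increases were those of Fpr2 and Saa3. Fpr2, a formyl peptide receptor of phagocytes, was 5.33-fold higher, and Saa3, an acute-phase serum amyloid gene, was 4.79-fold higher. The monocyte-attracting chemokine genes Ccl12 and Ccl2 were 3.03-fold and 2.72-fold higher. Gpr84, a fatty acid receptor of myeloid cells, was 2.90-fold higher, and Mmp3, which encodes stromelysin 1, was 2.66-fold higher. The other measured genes among the 12 largest increases were Slco4a1, an organic anion transporter (4.22-fold), Prr7 (4.02-fold), Pigt (3.02-fold), the amino acid transporter gene Slc43a2 (3.02-fold), the lectin gene Clec2d (2.93-fold) and Insyn1 (2.74-fold). Against robust SDs between 0.22 and 0.38 for genes of like brightness, the log2 differences of these 12 genes ran from 1.41 for Mmp3 to 2.41 for Fpr2.

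The largest measured decrease was that of Clec7a, the beta-glucan receptor Dectin-1 of phagocytes, which was 5.80-fold lower. Its other 2 probes detected on both arrays differed by -2.05 and -1.88 on the log2 scale. Cdh11, a cadherin of mesenchymal cells, was 3.16-fold lower, and Grem1, a secreted antagonist of bone morphogenetic proteins, was 3.05-fold lower. Arhgap35, a GTPase-activating protein, was 3.48-fold lower. Gnas, which encodes the stimulatory G protein alpha subunit, was 2.52-fold lower at a high signal (12.61 in control, 11.28 with EMF and AuNPs). The remaining 7 of the 12 largest decreases were Plpbp (2.98-fold), Pank3 (2.96-fold), Spin1 (2.85-fold), Susd2 (2.57-fold), Zc3h13 (2.51-fold), Mpp5 (2.49-fold) and Atxn3 (2.46-fold). A second detected probe differed by -1.75 for Plpbp and -1.44 for Cdh11, but by -0.78 for Gnas and -0.44 for Spin1.

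Among genes detected with EMF and AuNPs alone, Dctn1, a dynactin subunit, was at least 9.53-fold higher and the casein kinase gene Csnk1g1 at least 7.48-fold higher. Both bounds hold for the background correction used here and were smaller without it. The value for Dctn1 rests on 1 probe, with an intensity of 171 in control and 883 with EMF and AuNPs, so no second probe could check it. Mbd4, Traf2 and Dapk2 were at least 2.54-fold, 2.46-fold and 2.12-fold higher. A second probe of Csnk1g1 was likewise detected with EMF and AuNPs alone, and another on neither array, like the second probes of Slco4a1 and Arhgap35. Among genes detected in control cells alone, Ncald was at least 4.31-fold lower, Lrrn4cl 3.90-fold, Cavin1 2.71-fold, Npy1r 2.36-fold and Pcdh10 2.36-fold.

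**Figure D1:**
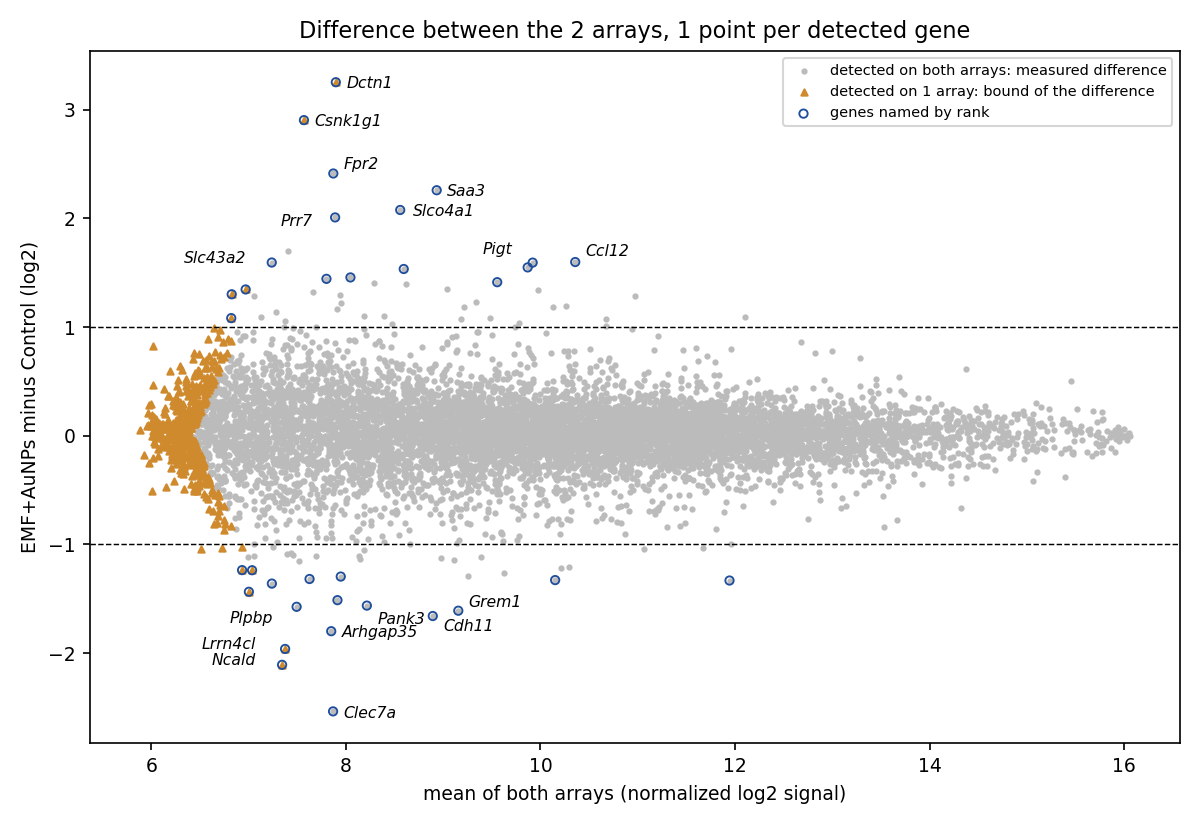
Each point is 1 of the 8651 detected genes, with the mean normalized log2 signal of both arrays on the x axis and the log2 difference, EMF and AuNPs minus control, on the y axis. Dashed lines mark the 2-fold limit, triangles are bounds for genes detected on 1 array, and circles are genes named by rank; the spread is widest among dim genes, and Dctn1 has the highest value and Clec7a the lowest.

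A second probe detected on both arrays existed for 8 of the higher genes and 9 of the lower ones, and it went the same way for each of them. It passed 2-fold for 5 of the higher and 4 of the lower genes. In simulated arrays, 74 of 10099 unchanged genes passed 2-fold and 0 passed 3-fold. In the data, 87 of 8651 genes passed 2-fold and 16 passed 3-fold. The simulated noise counted background noise on top of the observed spread and had no heavy tails. It therefore does not measure how many calls in the data are noise. Without background correction, which is the form of the deposited log2 values, 24 genes were higher and 16 lower, and 24 and 15 genes passed 2-fold under every normalization tried. Of the genes named so far, Ccl2, Slc43a2, Mbd4, Traf2, Dapk2, Susd2, Mpp5, Atxn3, Cavin1, Npy1r and Pcdh10 had a difference or bound under 2-fold with at least 1 of them. Other folds given above shrank by over 1.5 times without background correction, with log2 differences or bounds of 2.30 for Dctn1, 2.00 for Csnk1g1, 1.67 for Fpr2, 1.40 for Prr7, -1.76 for Clec7a, -1.34 for Ncald and -1.23 for Lrrn4cl. Saa3, at 1.86, then exceeded Fpr2.

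Interferon-stimulated genes were higher as a group with EMF and AuNPs. Of 19 detected members, 18 had a difference above 0, 10 passed 1.5-fold and 4 passed 2-fold, and none passed either limit downwards. The 4 were Usp18, a deconjugating enzyme of ISG15 (2.35-fold), Oasl2 (2.28-fold), the antiviral gene Rsad2 (log2 difference 1.10) and Irf7, a transcription factor of the interferon response (1.05). Usp18 and Oasl2 passed 2-fold under every normalization tried, while without background correction Rsad2 differed by 0.85 and Irf7 by 0.66. The list's median difference was 0.60 and exceeded that of every one of 10000 matched random lists, which lay between -0.11 and 0.18 at the percentile limits. Inflammatory cytokines and chemokines showed a median of 0.46, which also exceeded all random lists. Of 18 detected members, 8 passed 1.5-fold higher and 2 of these 2-fold (Saa3 and Ccl2), and none passed either limit downwards. Ccl5 and Cxcl5, both chemokine genes, differed by 0.96 and 0.92. Over random lists, the shift of the interferon list was 0.56 and fell to 0.42 without background correction and to 0.24 with no detection filter and no bounds, and that of the inflammatory list was 0.41 and fell to 0.26 without background correction. Of the inflammatory members, 6 were detected on 1 array only and enter with a bound, as does 1 interferon member, Mx2, whose bound of 0.60 is that list's median; it is named after its value was seen.

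Markers of macrophages and leukocytes were detected in these cultures too, 14 of the 15 on the array. The lysozyme gene Lyz2, named after its values were seen, had a normalized log2 signal of 15.49 in control and 15.38 with EMF and AuNPs. The pan-leukocyte antigen gene Ptprc was detected in control alone, by a dim probe with a bound of -0.51. Its other probe, detected on neither array, differed by 0.08. The median of the detected members was 0.07 (percentile 84.9), with 10 above 0 and 4 below. None passed 2-fold and 1, Cd52, passed 1.5-fold with a difference of 0.80. When all detected probes of a gene were averaged, the list lay at percentile 99.7, with a shift of 0.16 over random lists.

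**Figure D2:**
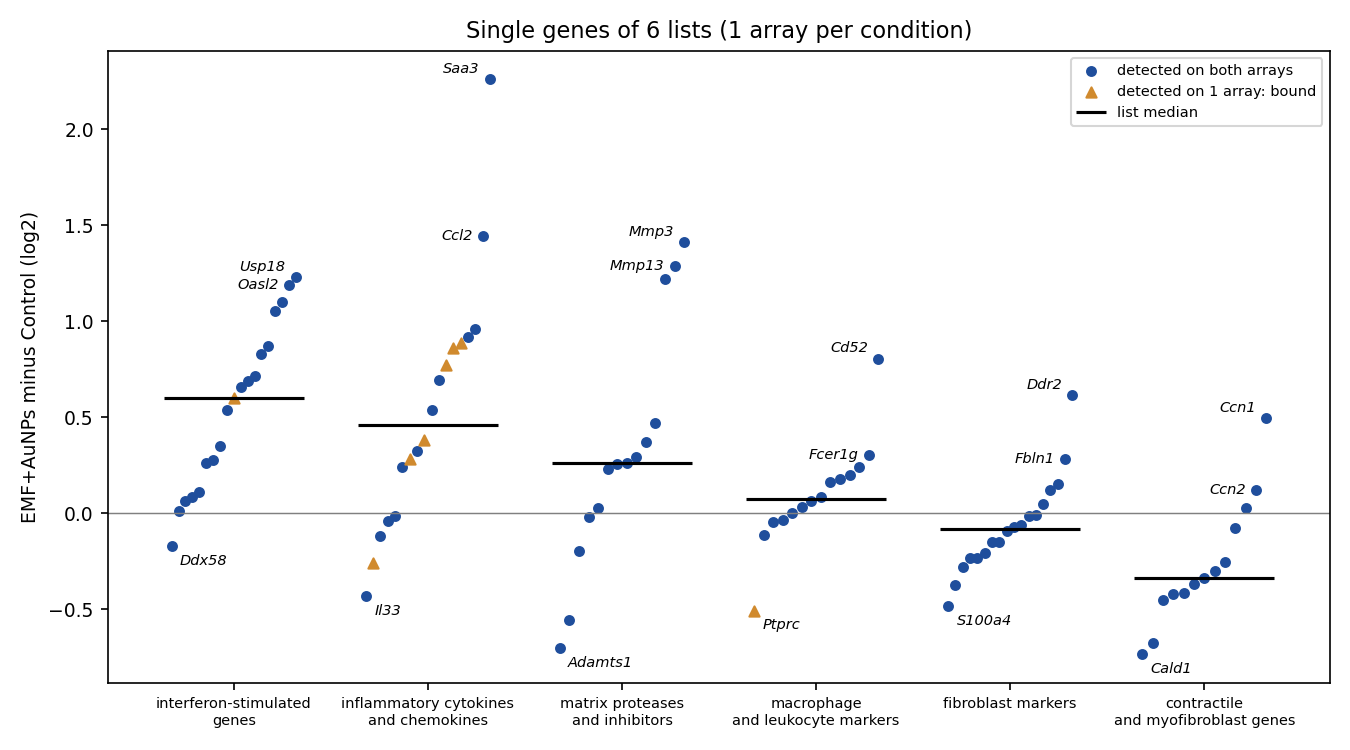
Log2 differences, EMF and AuNPs minus control, of the detected genes of 6 lists, sorted within each list, with the list median as a bar and bounds as triangles. The medians are 0.60 for interferon-stimulated genes, 0.46 for inflammatory cytokines and chemokines, 0.26 for matrix proteases and inhibitors, 0.07 for macrophage and leukocyte markers, -0.08 for fibroblast markers and -0.34 for contractile genes.

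Genes of matrix turnover and of the contractile apparatus moved in opposite directions. Of 14 detected matrix proteases and inhibitors, 3 passed 2-fold higher: Mmp3, the collagenase gene Mmp13 (1.29) and the gelatinase gene Mmp9 (1.22). Without background correction Mmp9 differed by 0.87, under 2-fold, while Mmp3 and Mmp13 stayed past it. The list's median was 0.26 (percentile 99.98), and 1 member, Adamts1 at -0.70, passed 1.5-fold lower. Contractile and myofibroblast genes had a median of -0.34, below every random list, with 10 of 13 detected members below 0. By the brightest probe, none passed 2-fold and 2 passed 1.5-fold lower: Cald1, which encodes the actin-binding protein caldesmon (-0.73), and the calponin gene Cnn2 (-0.67). Second probes differed by -1.17 for Cald1, past 2-fold, and by -0.37 for Cnn2. The 3 members above 0 were Ccn1 (0.49, other probes at -0.57 and 0.10), Ccn2 (0.12) and Acta2 (0.03). Ccn2 and Acta2 were named after their values were seen. The probes of Tpm2 disagreed, at -0.45 and 0.42. Fibroblast markers shifted less, with a median of -0.08 (percentile 2.22) and 13 of 18 members below 0. None passed 1.5-fold lower and 1, the collagen receptor gene Ddr2, passed it higher at 0.61. Among the others, the intermediate filament gene Vim differed by -0.37, S100a4 by -0.49, Col1a1 by -0.15 and Thy1 by 0.05. Collagen chains outside that list had a median of -0.15 (percentile 1.10), with Col15a1 at -0.77 and Col5a3 at -0.72. The other matrix genes lay at -0.07 (percentile 3.52), with 1 of 18 past 2-fold lower, Thbs1 at -1.04, which encodes thrombospondin 1 and differed by slightly under 2-fold without background correction.

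A total of 6 lists lay above the upper percentile limit and 6 below the lower one. Among lists of randomly drawn genes, about 1.03 of 41 would lie past each limit. Genes of a list that vary together between any 2 cultures pass the limits more often, and some lists are related. The comparison with 1.03 therefore does not measure an excess over chance between 2 cultures. Beyond those given above, skeletal and cardiac muscle genes were higher, with a median of 0.31 (percentile 99.9). Of the 12 detected, 4 passed 1.5-fold, namely Mylpf (0.86), Tnnt1 (0.64), Tnnc1 (0.63) and Myl1 (0.60). Replication-dependent and variant histones had a median of 0.15 (percentile 99.6), though these probes belong to a family of near-identical genes. Mitosis genes had a median of 0.13 (percentile 97.6), with 12 of 14 members above 0 and none past 1.5-fold. Adipocyte and fatty acid synthesis genes were lower, with a median of -0.23 (percentile 0.03). Of 14 detected members, 10 lay below 0 and 4 above, and 2 entered with a bound. Only 1 passed 1.5-fold, Pparg, the adipogenic nuclear receptor gene, at -0.59. Wnt signalling genes had a median of -0.10 (percentile 1.72), with 14 members below 0 and 6 above. Lrp6 (-0.94) and Sfrp1 (-0.91) passed 1.5-fold lower and Wnt4 (0.63) higher. The unfolded protein and integrated stress response list lay at -0.07 (percentile 2.45), and its members diverged, from Phgdh at -0.90 to Hspa5 at 0.60. The calls of the fibroblast marker, Wnt, stress response, mitosis and histone lists were lost under at least 1 alternative setting. With the setting used here counted, the mitosis call held in 6 of 13 settings and the stress response call in 6 of 14. Those of the fibroblast marker, Wnt and histone lists held in 8, 9 and 12 of 13. The other 7 calls held under all settings that could score them, although the shift over random lists shrank from 0.27 to 0.14 for muscle genes and from -0.26 to -0.17 for adipocyte genes at its smallest. Conversely, the lists of other matrix genes, chromatin remodelling complexes, p53 targets, heat shock genes, lysosomal genes, ribosomal proteins and transforming growth factor beta signalling, given elsewhere as within the limits, lay below the lower limit under at least 1 alternative.

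**Figure D3:**
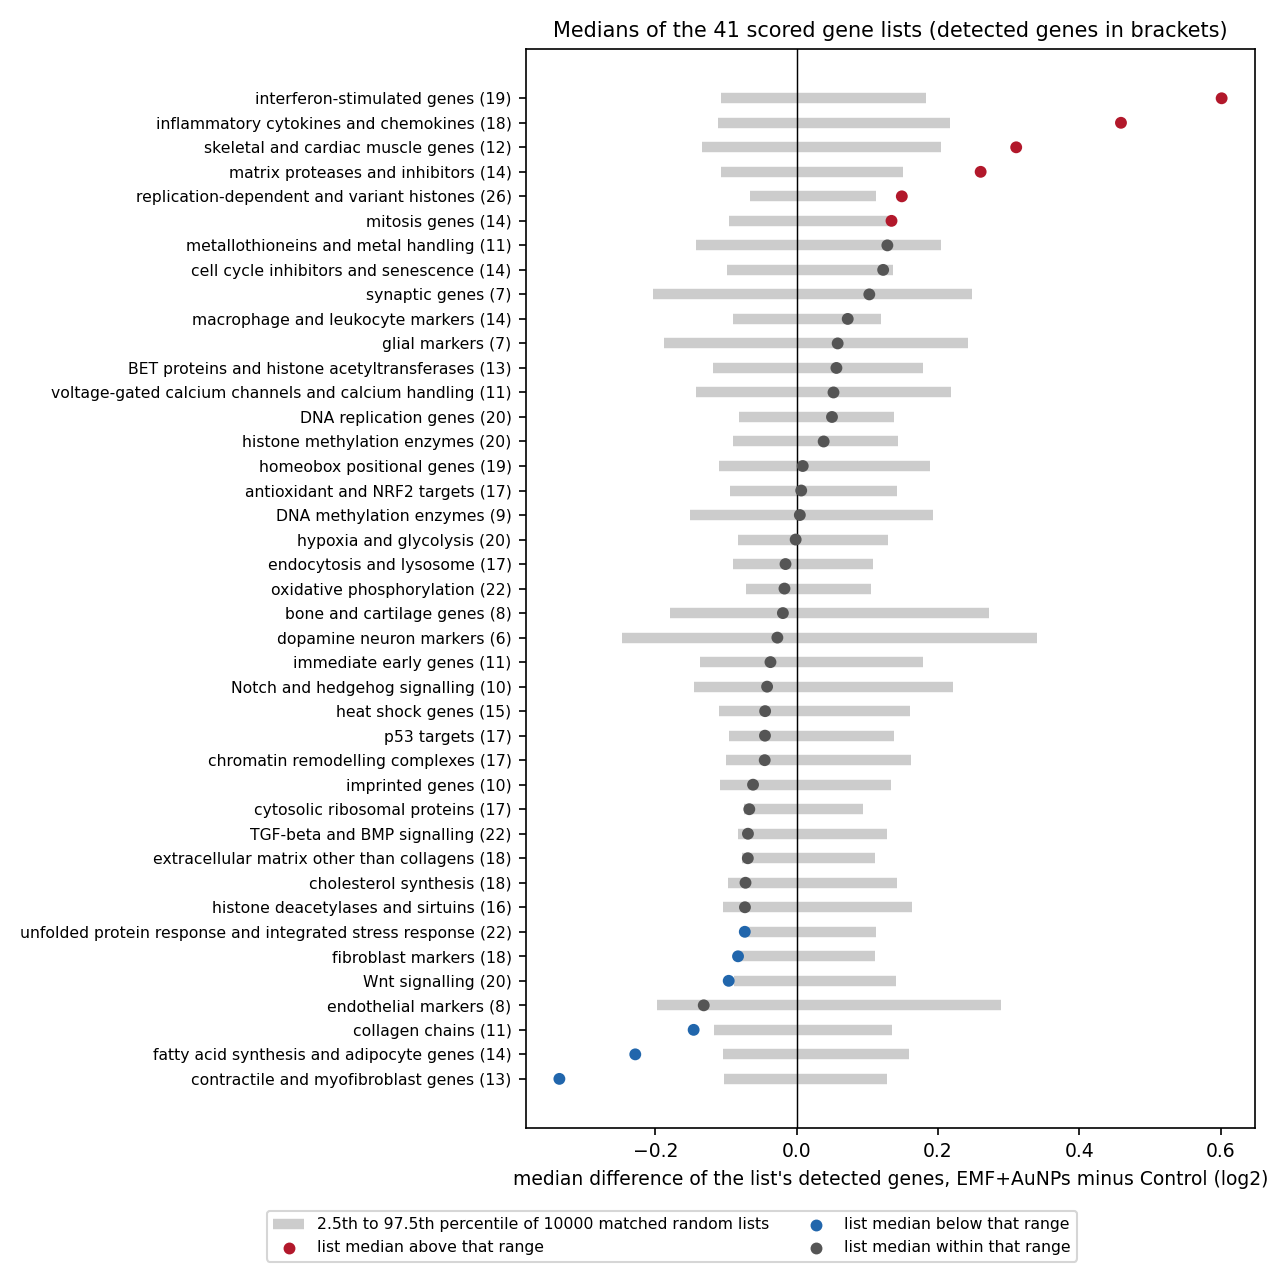
Median log2 difference, EMF and AuNPs minus control, of each of the 41 scored gene lists (points) beside the range of 10000 matched random lists between the percentile limits (grey bars). The highest median is that of interferon-stimulated genes at 0.60 and the lowest that of contractile genes at -0.34.

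Genes of the dopamine neuron lineage were asked about because of the study's aim. Th, Slc6a3, Slc18a2, Pitx3, Lmx1a and Foxa2, which mark or specify dopamine neurons, were not detected on either array, nor was the neuronal tubulin gene Tubb3. Nr4a2 and Ddc were detected at low signal and differed by 0.14 and 0.19, within the robust SD of 0.37 for genes of like brightness. Of 19 dopamine neuron genes on the array, 6 were detected, with a median of -0.03 (percentile 26.2). Gch1, the first enzyme of tetrahydrobiopterin synthesis, differed by 0.92 and the monoamine oxidase gene Maob by -0.98, neither past 2-fold. Pan-neuronal markers (4 of 19 on the array), proneural and neural progenitor factors (4), pluripotency genes (3), potassium and sodium channels (4), epithelial markers (4), erythroid genes (2) and sex-linked genes (4) had too few detected members to be scored. Map2 differed by -0.12. Kcnk1, a potassium channel gene, was past 2-fold higher at 1.14, but differed by 0.69 without background correction. Synaptic genes (median 0.10, percentile 72.9) and glial markers (0.06, percentile 60.1) lay within the range of random lists.

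The lists of chromatin regulators lay within the percentile limits. Bromodomain and histone acetyltransferase genes had a median of 0.06 (percentile 63.9), with none of 13 past 1.5-fold by their brightest probe. Brd2, a bromodomain protein that binds acetylated histone H4, has 3 probes, all with a detection p of 0 on both arrays. The brightest, ILMN_2751505, differed by 0.06 and ILMN_3154409 by 0.02. The third, ILMN_2734848, rose from an intensity of 2330 to 5945, a difference of 1.43 or 2.69-fold, and by 1.39 in the deposited log2 values. Kat2b, a histone acetyltransferase gene, differed by -0.57 on its brightest probe and by -1.55 on another. Histone deacetylases and sirtuins lay at -0.07 (percentile 6.09), histone methylation enzymes at 0.04 (55.1), DNA methylation enzymes at 0.00 (percentile 38.0) and chromatin remodelling complexes at -0.05 (12.5). The last lay at percentile 1.82 with no detection filter and no bounds. Among its members, the histone-binding protein gene Rbbp7 differed by -0.86 on its brightest probe and by -1.08, -0.97 and 0.19 on 3 others.

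**Figure D4:**
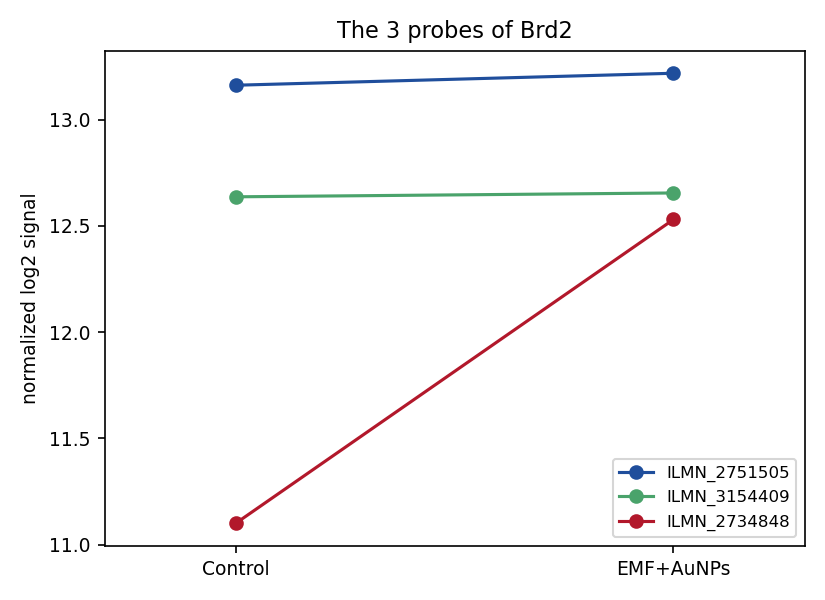
Normalized log2 signal (y axis) of each of the 3 Brd2 probes on the control and the EMF and AuNP array (x axis), 1 array per condition. ILMN_2734848 rises by 1.43 while the other probes differ by 0.06 and 0.02.

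Antioxidant genes had a median of 0.01 (percentile 36.7), but Hmox1, the haem oxygenase gene, was 2.33-fold lower. Metallothioneins and metal handling genes lay at 0.13 (88.5), with Tfrc at 0.53 and Atp7a at -0.50. Medians of heat shock genes (-0.04, percentile 14.0), p53 targets (-0.04, 12.1) and immediate early genes (-0.04, 20.4) were close to 0, with Cryab at -0.81 the largest change of the heat shock list. Cell cycle inhibitors lay at 0.12 (96.1), with Cdkn2a and Cdkn1b at 0.82 each, and DNA replication genes at 0.05 (65.2). Lysosomal genes lay at -0.02 (24.8), glycolysis at 0.00 (28.3), oxidative phosphorylation at -0.02 (18.7), cholesterol synthesis at -0.07 (5.61) and cytosolic ribosomal proteins at -0.07 (3.80). Among signalling lists, the transforming growth factor beta list lay at -0.07 (4.21) and the Notch and hedgehog list at -0.04 (17.7), and calcium channels lay at 0.05 (55.8). Endothelial markers lay at -0.13 (7.08), bone and cartilage genes at -0.02 (27.4), homeobox genes at 0.01 (34.7) and imprinted genes at -0.06 (9.59). The reference genes Actb, Gapdh and Hprt differed by 0.12, 0.03 and 0.09 on their brightest probes, although other probes of Actb ran from -0.33 to 0.96.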

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

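Probes with no gene name in the annotation used here took no part in the comparisons, and 2 of the 657 such probes detected on both arrays were at least 2-fold higher with EMF and AuNPs. They stand out only as signal outside the reported genes that exceeded the control array. Another 3 were at least 2-fold lower, and the differences ran from -1.25 to 1.15. No explanation was tested for them.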

How the results depend on the processing

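The counts of 45 higher and 42 lower genes depended on the background correction, the detection filter and the fold limit. They were 27 and 21 with normexp without negative controls and an offset of 50, and 24 and 16 with no background correction or with the deposited log2 values. The first of these changed the background model and the offset together. Dim genes, whose differences spread most, supplied most of the calls, 36 of the higher and 35 of the lower genes lying below the median brightness. A detection p under 0.05 gave 73 higher and 48 lower genes, and no detection filter together with no bounds gave 96 and 64. The cause was not tested for any of these shifts. Limits of 1.5-fold and 3-fold gave 289 and 252, and 10 and 6. Of 3 alternatives chosen after seeing the data, a count by any probe detected on both arrays gave 51 and 87. Restriction to the 1792 genes whose 2 brightest detected probes agree within 0.5 gave 5 and 5, with 1 list above and 0 below the percentile limits, as fewer genes and lists were left. Measured differences in place of bounds left 5 lists above and 6 below. Median centring, cyclic loess, genes detected on both arrays and averaged probes kept both counts within 1.5-fold. The list counts of 6 and 6 ran from 4 to 6 and from 4 to 8 under the other settings. Of 499 list values under alternatives, 470 moved by less than 1 SD of their random lists, and 0 called lists changed side. Of 2021 values of named genes, 1918 moved by less than the robust SD of like genes, and 0 past 2-fold changed sign. No paired analysis was possible because each condition has 1 array, and no array could be left out for the same reason.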

Other observations

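The tests of macrophage share, normalization, dim probes, fibroblast share and the brightness of the Brd2 probes were chosen after the results they bear on had been seen. Some genes with known roles in immune cells, outside the fixed lists, were among the 45 higher genes; they were picked after their values were seen, and no enrichment was tested. Siglec1, an interferon-inducible receptor of macrophages, was 2.63-fold higher, and Ifi27l2a and Ifi47, both interferon-responsive, were 2.13-fold and 2.00-fold higher. Havcr2 (2.12-fold), the B-cell activating factor gene Tnfsf13b (2.14-fold), Ncf1, a subunit of the phagocyte oxidase (2.04-fold), and Ch25h, which makes 25-hydroxycholesterol (2.01-fold), were higher too. Siglec1 and Ifi27l2a passed 2-fold under every normalization tried, and the other genes named here were under 2-fold with at least 1 of them. In the other direction, the phagocyte receptor gene Clec7a was 5.80-fold lower, and Hmox1, a member of the antioxidant list, was 2.33-fold lower.

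Xist was detected on both arrays together with the Y-linked genes Eif2s3y, Kdm5d and Uty. These 3 differed by 0.18, 0.26 and 0.17, and the 2 probes of Xist by 0.48 and 1.70. Across the 2054 genes with at least 2 probes detected on both arrays, the differences of the brightest 2 correlated with Pearson's r = 0.47 and a Spearman coefficient of 0.40. This correlation is across genes, which are not independent replicates. In 35 genes (1.70%) both probes lay at least 1 (log2) apart.

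Interferon-stimulated and inflammatory genes were higher with EMF and AuNPs, with list medians of 0.60 and 0.46. A larger share of macrophages is argued against as the whole cause by the median of their markers, 0.0723. This median lies 0.39 under the smaller list median, against an SD of 0.28 among the markers. A smaller rise in their share stays open, as averaging all probes left the markers 0.16 above random lists. The markers were also brighter, with a median log2 signal of 12.75 against 9.34 for the interferon list and 7.53 for the inflammatory list. Whether bright probes understate a change was not tested, which limits this comparison. The normalization is argued against as the whole cause by the interferon list, whose shift over random lists was at least 0.42 under 5 other normalizations (0.56 here). Of these, the deposited values repeat the form without background correction. The size of the shift depends on the background correction. Dim probes alone are argued against for the interferon list by its 7 brighter members, which had a median of 0.28. The inflammatory list was not tested in this way. It is dimmer, with a median signal of 7.53 and 6 of 18 detected members at a bound, so dim probes stay open for it. As a hypothesis, a change in the activation state of macrophages may contribute, though its predictions were met only in part. A list of classical activation genes, 0 of them in the fixed lists, lay at percentile 99.8 (14 detected, median 0.29), with 11 above 0 and 3 below. Many genes of this kind respond to interferon and inflammatory signals, so the list is not independent of the 2 lists already seen to be higher. Its rise therefore does not tell macrophage activation from a response of other cells. Among the 3 below were Cd86 at -0.56 and Cd80 at -0.37, named after their values were seen. Resident or alternatively activated genes were predicted to be lower but leaned higher (18 detected, 13 above 0 and 5 below, 1 in the fixed lists, percentile 94.1), which argues against that part. Which cells of the cultures carried the change was not measured. The field, the particles and a chance difference between 2 cultures all stay open, since each condition has 1 array.

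Contractile genes were lower, with a list median of -0.34. A smaller share of fibroblasts stays open: the fibroblast markers were lower too, by a median of -0.0829 (percentile 2.22, a call that held in 8 of 13 settings, with Ddr2 at 0.61 the only member past 1.5-fold), and the distance of 0.25 to the contractile median is no larger than the SD of 0.25 among the markers. As a hypothesis, lower activity of serum response factor, which drives many contractile genes, may contribute. Many of its listed targets are genes of the actin cytoskeleton, as contractile genes are, so the target list is not independent of the contractile list. The list of targets, 0 of them in the fixed lists, lay at percentile 0.1 (17 detected, median -0.17), with 12 members below 0 and 4 above. The ends, Fhl1 at -0.42 and Csrp2 at 0.35, and the factor's own gene Srf, a member at 0.03, were named after their values were seen, and the factor's activity was not measured. Immediate early genes, some of which this factor also drives, were not lower as a list (median -0.04, percentile 20.4). Of these, 5 lay above 0 and 6 below, with Fos at 0.47 and Egr2 at -0.39. In the contractile list, Ccn1, Ccn2 and Acta2 lay above 0, against 10 members below. The hypothesis is thus met only in part.

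One Brd2 probe was 2.69-fold higher and the other 2 differed by 0.06 and 0.02, a gap of 1.41. Among other genes, 0 of 583 probe pairs of at least like brightness (to within 1 log2 unit) differed by as much. However, the gap of 1.41 is the widest among the 3 Brd2 probes, while pairs of other genes were not chosen by their gap. The comparison is uneven, so noise between probes is not excluded. A dim probe is argued against, as 0 of the Brd2 probes that rose lay near background. The probe that rose had an intensity of 2330 in control, against a median of 917 among detected probes. A change in 1 transcript form and cross-hybridization of 1 probe stay open and were not tested, as probe sequences were not used here.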
